A study of Mus musculus with 4 samples.

How the data were processed

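RNA sequencing was made of 4 libraries of sorted cells from the embryonic mouse cortex, 2 from cortices electroporated with a ZsGreen control plasmid and 2 from cortices electroporated with a plasmid for Zeb1 and ZsGreen. Per the labels' protocols, electroporation was at E14.5, and 48 hours later the cortex was dissociated with papain, fluorescent cells were sorted, and RNA was extracted with Trizol. Per the labels, the libraries were sequenced on a BGISEQ instrument. The deposited table gives FPKM per gene and library, as the authors made them, and not read counts. Per the submitters' processing notes, STAR, Cufflinks and DESeq2 were used with genome build GRCm38, without versions or the role of each tool. Count-based models were therefore not fitted here.

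The table held 48395 genes and 1 emptied line. A spreadsheet had turned 27 gene names into dates, and all 27 were restored from the gene identifiers. Of the identifiers, 47930 were matched to the GENCODE gene table, and 67 were repeated. For a symbol with more than 1 entry, the longest locus was taken. Gene starts in the table were counted from 0, since 43309 loci had a GENCODE start 1 above the table's, and 1 was added. The absolute depth is unknown, so no counting interval or detection floor was computed. Relative depth was estimated from genes shorter than 200 bp with values above 0 in both libraries compared. The most common ratio of their values to those of control replicate 1 was taken as the ratio of single-read values. It was held by 63 of 81 genes for control replicate 2, 73 of 95 for Zeb1 replicate 1 and 70 of 98 for Zeb1 replicate 2. Only ratios near 1 were searched, so a large difference in depth could not have appeared.

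Zeb1 and control libraries were compared with limma 3.58.1 (statmod 1.5.0) in R 4.3.3 on log2(FPKM + 1), with values as deposited. Genes with a mean of at least 1 FPKM over the 4 libraries were tested, 14330 in all. The moderated test was two-sided, with an intensity trend, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are Zeb1 minus control on that scale. An exact permutation test of 2 against 2 libraries cannot give a p under 0.333, so none is given. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

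In all, 38 gene lists, 16 of cell types and 22 of pathways, and 23 genes of the study question were fixed before the data were examined, as were the test, the filter, the naming rule and the alternatives, except where stated. Of the 834 list genes, 820 were in the table under their symbols and 653 were tested. Of the 23 study genes, 22 were in the table and 20 were tested. Tubb3 was not found under its symbol and is not analysed here. The 35 lists with at least 5 tested genes were tested with camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01, with adjustment over the lists. Camera was also run with an estimated correlation and with ranks, and fry was run as a test of each list on its own. Counts adjusted over the list alone use only the p-values of that list's genes.

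The naming rule took Zeb1, then up to 15 genes per direction among those that passed and had both Zeb1 libraries on the same side of both controls, by size of change and then, where fewer passed, by the smallest p. Gene models without a proper name were left out. It then took up to 4 members of each list by p and the genes of the study question. After the data were seen, the protein-coding genes were also tested alone, and the rule was applied to them as well. Single genes outside the rule are stated to be chosen after their values were seen.

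The alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, each library rescaled to the same total, median-of-ratios scaling, quantile normalization, limma without the trend and with robust moderation, a replicate block, a minimum change of 2-fold, and leaving out each library in turn. The lone library of a group is then assumed to vary like those of the other group. The steps were tested on simulated data with 200 changed genes in each of 20 simulations. Over all genes, 0% of 2-fold, 21.5% of 4-fold and 52.7% of 8-fold changes were called, with a mean of 3.45 unchanged genes called per simulation. Over protein-coding genes alone, the shares were 11.4%, 87.0% and 96.1%, with 7.55 unchanged genes called. Lists of 20 genes shifted by 0.25 on the log2 scale were called, at an unadjusted p under 0.05, in 18 of 20 simulations with the preset and in 2 of 20 with the estimated correlation, and lists shifted by 0.50 in 20 and 19. Unshifted lists were called with the preset correlation in 0, 1 and 3 of 20 simulations beside shifts of 0.25, 0.50 and 1.00. The simulated genes varied independently of each other. These shares therefore do not cover lists whose members move together between libraries, such as the microglial list.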

Results

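RNA was measured in 4 libraries of cells sorted from the embryonic mouse neocortex. Cortices of ICR mice were electroporated in utero at E14.5. The plasmid carried either the green fluorescent protein ZsGreen alone or Zeb1 together with ZsGreen, both driven by the ubiquitous CAG promoter. After 48 hours, at E16.5, the cortices were dissociated and the fluorescent cells were sorted. The control and the Zeb1 group held 2 libraries each. ZEB1 is a zinc-finger transcriptional repressor, best known for promoting the epithelial-to-mesenchymal transition, and the comparison asks which transcripts differ in cortical cells that overexpress it, with neural differentiation and cell migration in view. The table gives FPKM, so the absolute depth of the libraries is unknown. Relative depth was estimated from short genes, as the most common ratio of their values between libraries among ratios near 1. Against control replicate 1, it was 1.01 in control replicate 2, 0.994 in Zeb1 replicate 1 and 1.04 in Zeb1 replicate 2. The labels do not say whether the replicates come from separate litters, so the p-values measure only the spread between these samples. Between 13647 and 13997 genes per library reached 1 FPKM. Over the protein-coding genes tested, the Spearman correlation across genes was 0.972 between the controls and 0.9755 between the Zeb1 libraries. It ranged from 0.9446 to 0.9754 between libraries of different groups. Control replicate 1 correlated more with Zeb1 replicates 1 and 2 (0.9754 and 0.973) than with control replicate 2, so the libraries did not group by condition on this measure.

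Zeb1 itself separated the groups by far. It lies on chromosome 18 of GRCm38, positions 5591860 to 5775467, and rose from 26.9 ± 11.7 FPKM (SD, n = 2) in control cells to 5925 ± 428 FPKM (SD, n = 2) in Zeb1 cells. The log2 fold change on the log2(FPKM + 1) scale was 7.80 with a standard error of 0.35, and the limma adjusted p was 0.0192. FPKM per gene do not separate plasmid from endogenous transcripts. Besides Zeb1, only Ebf3 and Cacna1g among the protein-coding genes passed the test over all 14330 genes. Ebf3 (chromosome 7, 137193673 to 137314445) encodes a helix-loop-helix transcription factor of early neurons and rose from 1.34 ± 0.310 to 23.5 ± 1.27 FPKM, a log2 fold change of 3.39 with a standard error of 0.18 and an adjusted p of 0.0273. Cacna1g (chromosome 11, 94408391 to 94474198) encodes the pore subunit of a T-type calcium channel and rose from 5.17 ± 0.0809 to 74.7 ± 17.5 FPKM, a log2 fold change of 3.60 with a standard error of 0.21 and an adjusted p of 0.0374. Both genes were higher in both Zeb1 libraries than in both controls. The Ebf3 and Cacna1g calls over all genes ended without a filter (adjusted p of 0.229 and 0.239) and with a replicate block (0.0925 and 0.104), and that of Zeb1 ended under both as well. The Cacna1g call also ended with rescaling to the same total (adjusted p = 0.0519), median-of-ratios scaling (0.0581), quantile normalization (0.0574) and limma without the trend (0.0526), with log2 fold changes of 3.57 to 3.71.

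In all, 12 genes were higher and 16 were lower in Zeb1 cells at an adjusted p under 0.05, and 25 of these 28 were noncoding genes shorter than 200 bp. The 9 short genes that were higher included Mir6988, Mir3100, Mir6925, Mir7070 and Mir6386, and 8 of the 9 were listed at 0 in both controls. The 16 that were lower were all short noncoding genes listed at 0 in both Zeb1 libraries, among them Snord53, Mir1981, Mir7578, Mir7067, Mir877, Mir24-2 and Mir1b. For 24 of the 25 short genes, the nonzero values of the 2 replicates stood in a ratio of whole numbers up to 4 once relative depth was removed, within a tolerance of 0.5%. Among 242 short genes that were not called and had values in both controls, the share was 62.8%. No fold is given for the called short genes. Testing the 11916 protein-coding genes alone, a choice made after the data were seen, called the same 3 genes higher, with adjusted p of 0.00318 for Zeb1 and 0.00938 for Ebf3 and Cacna1g, and called 0 lower. At an unadjusted limma p under 0.05, 582 protein-coding genes were higher and 547 lower. After the results were seen, the 4 libraries were also split into pairs that ignore the group. Those splits gave 765 and 97 such genes over both directions, against 1129 for the real split. Leaving out any 1 of the 4 libraries ended the calls over all genes, with an adjusted p for Zeb1 of 0.116 to 0.330, for Ebf3 of 0.139 to 0.343 and for Cacna1g of 0.106 to 0.392. The Zeb1 log2 fold change itself stayed between 7.35 and 8.24.

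**Figure D1:**
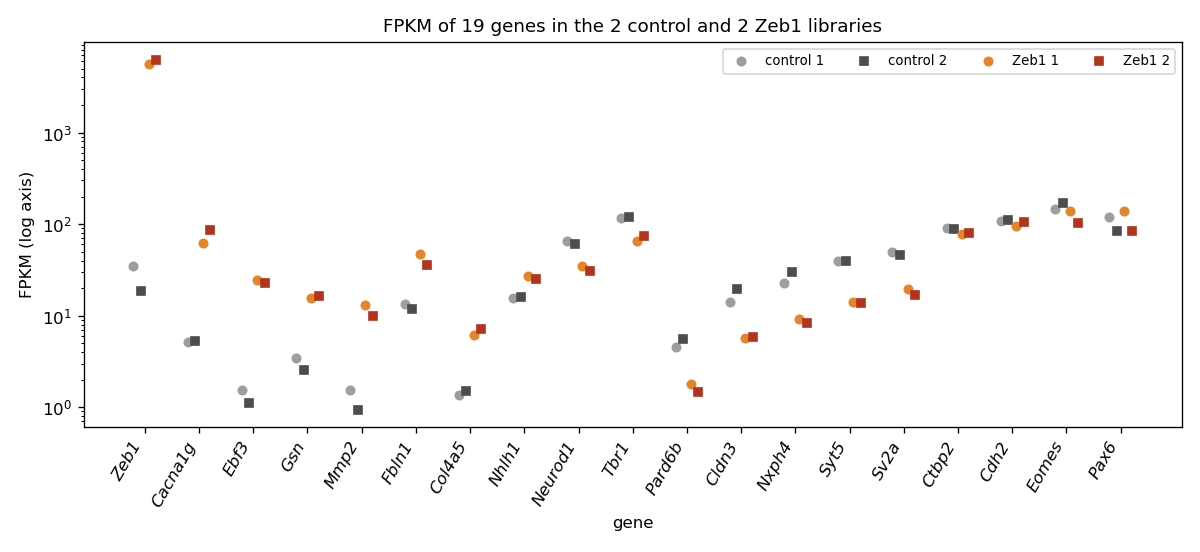
FPKM on a log axis for 19 genes, with 1 point for each of the 2 control and 2 Zeb1 libraries. Zeb1 lies at 18.6 and 35.2 FPKM in the controls and at 5622 and 6227 FPKM in the Zeb1 libraries, and Neurod1, Tbr1, Pard6b and Syt5 lie lower in both Zeb1 libraries than in both controls.

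The protein-coding genes that came next in order of p did not pass the test over all genes, and they were not tested for a shared function. On the higher side, Gsn, which encodes the actin-severing protein gelsolin, had 3.01 ± 0.619 FPKM in control and 15.9 ± 0.594 FPKM in Zeb1 cells. The gelatinase gene Mmp2 had 1.24 ± 0.429 and 11.5 ± 2.20 FPKM, and Fbln1, which encodes the matrix protein fibulin, had 12.7 ± 1.08 and 41.7 ± 7.97 FPKM. The neighbouring X-linked collagen IV genes Col4a5 and Col4a6 had log2 fold changes of 1.64 and 1.88. Those of Glipr2, Kcnab3 (a potassium channel beta subunit), Ppp1r14a, Ppp1r17, Lmcd1, Nrg2 (a neuregulin) and Lor (loricrin) ran from 1.79 for Glipr2 to 2.71 for Lor. For genes under 1 FPKM in control cells, the size of the change depends on the pseudocount. Lor had 0.251 and 7.25 FPKM, Ppp1r17 0.270 and 5.62 FPKM, Col4a6 0.326 and 3.88 FPKM, and Nrg2 0.407 and 4.38 FPKM, and with a pseudocount of 0.1 their log2 fold changes were 4.37, 3.92, 3.22 and 3.13. On the lower side, Syt5, a synaptotagmin of secretory vesicles, had 39.6 ± 0.570 FPKM in control and 14.0 ± 0.137 FPKM in Zeb1 cells. Sv2a, a synaptic vesicle membrane protein, had 47.9 ± 2.58 and 18.2 ± 2.17 FPKM, and Cxadr, an adhesion receptor of cell junctions, had 61.0 ± 2.01 and 28.5 ± 0.355 FPKM. Ica1, Ckmt1, Gipr, Nxph4, Shisa7, Jakmip1, Map3k9, Arg2, Tma7, Nme3, Cldn3 and Fam160a1 had log2 fold changes between -2.26 (Ica1) and -1.18 (Tma7). The limma adjusted p over all genes lay between 0.104 for Glipr2 and 0.394 for Fam160a1. All of these genes had both Zeb1 libraries on the same side of both controls. Of all 14330 genes tested, 37.6% did so, against 33.3% by chance. Genes chosen by small p are likely to separate in this way, so it adds no support.

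Among 20 genes of the study question that reached the level for testing, 3 besides Zeb1 passed when adjusted over the list alone, and all 3 were lower in Zeb1 cells. The list holds Zeb1 itself, the gene on the plasmid, and its small p eases the adjustment of the genes ranked after it. Neurod1, a proneural factor that drives neuronal differentiation, had 63.6 ± 3.58 FPKM in control and 32.7 ± 3.07 FPKM in Zeb1 cells (SD, n = 2 each), a log2 fold change of -0.94 with a standard error of 0.15 and an adjusted p of 0.0310 over the list alone. Pard6b, a member of the PAR polarity complex, had 5.06 ± 0.797 and 1.63 ± 0.233 FPKM, a log2 fold change of -1.20 and an adjusted p of 0.0365 over the list alone. Tbr1, a transcription factor of early-born deep-layer neurons, had 117 ± 1.69 and 69.8 ± 7.11 FPKM, a log2 fold change of -0.75 and an adjusted p of 0.0374 over the list alone. The Tbr1 call over the list alone ended at a mean of at least 5 FPKM, with median-of-ratios scaling, with quantile normalization and without the trend, with adjusted p of at most 0.0681. Over all genes tested, limma gave Neurod1, Pard6b and Tbr1 adjusted p of 0.367, 0.449 and 0.487, so only Zeb1 passed there. Leaving out any 1 library, which also ended the Zeb1 call over all genes, ended these 3 calls over the list alone. So did a replicate block in the limma fit over all genes (0.0544 for Neurod1, 0.0681 for Pard6b and 0.0681 for Tbr1). A replicate block in the fit of protein-coding genes alone, chosen after the data were seen, instead called all 3 genes. That fit leaves 1 residual degree of freedom. With a library left out, the adjusted p were 0.104 to 0.165 for Neurod1, 0.122 to 0.143 for Pard6b and 0.104 to 0.191 for Tbr1. For Zeb1, the adjusted p over the list alone was 0.000536 and lay between 0.0175 and 0.0682 with 1 library left out, past the threshold only without a control library.

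The other genes of the question did not pass over the list alone. The polarity scaffold Pard3 had a log2 fold change of 0.64 (adjusted p of 0.0523 over the list alone) and the intermediate filament gene Vim one of 0.75 (0.0942). Ctbp2 and Ctbp1, which encode corepressors that bind ZEB proteins, had log2 fold changes of -0.17 and -0.10, with 95% intervals of -0.53 to 0.19 and -0.80 to 0.61. Zeb2 had a log2 fold change of -0.21, the N-cadherin gene Cdh2 one of -0.14, and the adhesion gene Chl1 one of -0.32. Among progenitor genes, Pax6 had 0.11, Sox2 0.27, Nes -0.09, Hes5 0.05, Neurog2 0.11 and Eomes -0.38. Among neuronal genes, Bcl11b had 0.49 and Dcx 0.12. The signs of Ctbp1, Pax6, Dcx, Nes and Hes5 turned when single libraries were left out. Cdh1, the E-cadherin gene, reached at most 0.0704 FPKM and Snai2 at most 0.164 FPKM in any library, below the level for testing.

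Neuronal and progenitor lists fixed before the data were examined were tested as sets with camera, and 0 of these passed at an adjusted p under 0.05 with the preset correlation. At an unadjusted p under 0.05, 11 of all 35 lists passed. Genes of immature and migrating projection neurons came closest, with a median log2 fold change of -0.15 over 21 genes, 15 of them negative, and an adjusted p of 0.0645. Within it, the neuronal zinc-finger gene Myt1l had a log2 fold change of -0.57 and the netrin receptor gene Unc5d one of -0.60. The median was -0.17 for upper-layer neurons (adjusted p = 0.206), -0.16 for deep-layer neurons (0.235), -0.20 for synapse and excitability genes (0.188) and -0.05 for proneural and differentiation factors (0.569). It was 0.07 for apical radial glia (0.245), 0.21 for outer radial glia (0.206), 0.12 for intermediate progenitors (0.612) and 0.10 for interneurons (0.200). Without Zeb1 replicate 2, 4 of these lists passed. Immature neurons (median -0.16, adjusted p = 0.0153), upper-layer neurons (-0.23, 0.0107) and synapse genes (-0.17, 0.0164) were then lower and apical radial glia higher (0.29, 0.0441). Without Zeb1 replicate 1, their adjusted p were 0.305, 0.990, 0.716 and 0.990.

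Single members of the neuronal lists went both ways. In the deep-layer list, 4 of 17 genes were lower and 2 higher when adjusted over the list alone. Over all genes 0 passed in limma, against 2 higher and 5 lower at an unadjusted p under 0.05. The secreted synaptic ligand Nxph4 (adjusted p of 0.0255 over the list alone), Wnt7b (0.0318), Tbr1 (0.0318) and Ppp1r1b were lower, with log2 fold changes of -1.48, -0.69, -0.75 and -0.77. Lmo3 (0.0262) and Foxp1 were higher, with 0.94 and 0.76. Ppp1r1b and Foxp1 were chosen after their values were seen. In the proneural list, 2 of 24 were lower and 2 higher when adjusted over the list alone, each with an adjusted p of 0.0448. Over all genes 0 passed in limma, against 2 higher and 4 lower at an unadjusted p under 0.05. Neurod1 and Tbr1 were the lower pair, and Nhlh1 and Nhlh2, helix-loop-helix factors of newborn neurons, were higher, with log2 fold changes of 0.70 and 1.56. Among synaptic genes, 0 of 32 passed in limma over the list alone, against 1 higher and 6 lower at an unadjusted p under 0.05. The vesicular glutamate transporter Slc17a7, the complexin Cplx1 and synaptophysin (Syp) had log2 fold changes of -0.72, -0.63 and -0.47, and the NMDA receptor gene Grin1 had 0.61. Leaving out any 1 library ended every call over the deep-layer and proneural lists alone, with adjusted p of 0.0821 or more, and so did a replicate block, with 0.0573 to 0.0839.

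Epithelial genes were lower as a set and mesenchymal genes higher as a set with the preset correlation. With that setting, splits of the libraries into pairs that ignore the group called 9 and 5 lists, against 9 for the real split. The epithelial and mesenchymal lists were not among those, but the splits are too few to judge by. The 6 epithelial genes tested had a median log2 fold change of -0.42 (camera adjusted p = 0.0269), and 5 of the 6 were lower in both Zeb1 libraries than in both controls. Of all 14330 genes tested, 2789 were lower in this way. With pseudocounts of 0.5 and 0.1, the median was -0.54 and -0.71 (adjusted p of 0.0291 and 0.0248). The estimated correlation gave an adjusted p of 0.740 for this list and for the other 8 lists called with the preset correlation. The tight-junction claudin Cldn3 and Pard6b passed when adjusted over the list alone, at 0.0151 and 0.0164, with log2 fold changes of -1.37 and -1.20, and 0 of the 6 passed in limma over all genes, against 2 lower at an unadjusted p under 0.05. With 1 library left out, the adjusted p of both genes over the list alone lay between 0.0417 and 0.111, and they passed only without control replicate 1. Ranks in place of the moderated statistic ended the epithelial call (adjusted p = 0.1), and so did leaving out Zeb1 replicate 1 (0.0578) and a replicate block (0.0603). Without a filter, 36 of the 39 epithelial genes were tested, the median was -0.0097 and the adjusted p was 0.283, so the shift rests on the 6 that reached the level for testing. The 25 mesenchymal genes had a median log2 fold change of 0.42, with 20 of 25 positive (camera adjusted p = 0.00152, and adjusted p = 0.740 with an estimated correlation). With pseudocounts of 0.5 and 0.1, the median was 0.54 and 0.68 (0.00147 and 0.00116). Mmp2 passed when adjusted over the list alone, at 0.0152 (0.110 to 0.295 with 1 library left out), while Vim, Tnc (the matrix protein tenascin) and the receptor kinase Axl had log2 fold changes of 0.75, 0.54 and 1.29. Without control replicate 2, the mesenchymal median was 0.20 and the adjusted p was 0.0865. Like the microglial list, the list was lowest in control replicate 2 (-0.14 from the control mean) and highest in Zeb1 replicate 1 (0.63), and Axl had 18.8 and 9.02 FPKM in the controls and 37.6 and 29.6 FPKM in the Zeb1 libraries.

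Extracellular matrix and integrin genes also rose as a set, with a median log2 fold change of 0.28 over 31 genes (camera adjusted p = 0.0213, and adjusted p = 0.740 with an estimated correlation). Its tested members Fn1, Tnc, Itga5, Itgav, Mmp2, Mmp14, Sparc and Thbs1 are also on the mesenchymal list, so these set results share genes. Adjusted over the matrix list alone, 3 genes were higher and 1 lower. Over all genes 0 passed in limma, against 5 higher and 3 lower at an unadjusted p under 0.05. Mmp2, Col4a5 and Col4a6 were higher, each with an adjusted p of 0.0150, and the laminin-binding integrin gene Itga3 was lower, with a log2 fold change of -1.39 and an adjusted p of 0.0296. The list's call ended without control replicate 2, where the median was 0.06 (adjusted p = 0.113), without Zeb1 replicate 1 (0.0508) and at a mean of at least 5 FPKM (0.0549). Leaving out any 1 library also ended the 4 gene calls over this list, with adjusted p of 0.0680 or more.

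Lists for adhesion, polarity and migration did not pass with all 4 libraries. The 48 migration genes tested had a median log2 fold change of -0.03 (camera adjusted p = 0.612). Its members included the reelin adaptor Dab1 at -0.75, the small GTPase gene Rac3 at -0.49 and the chemokine receptor gene Ackr3 at 0.81. The 35 adhesion molecules of the immunoglobulin and cadherin families had a median of -0.10 (0.245), with Alcam at -0.71, Lrfn5 at -0.72, Cadm1 at 0.65 and Cadm3 at 0.62. Without Zeb1 replicate 2, the adhesion list passed as lower (-0.15, 0.0230). The median was 0.01 for axon guidance (0.569), with Dcc at 0.72, and 0.04 for apical-basal polarity complexes (0.612). In all 4 of these lists 0 genes passed, whether adjusted over the list alone or over all genes, and the limma counts at an unadjusted p under 0.05 were 1 higher and 3 lower for migration, 3 and 2 for adhesion, 1 and 1 for axon guidance and 1 and 1 for polarity.

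**Figure D2:**
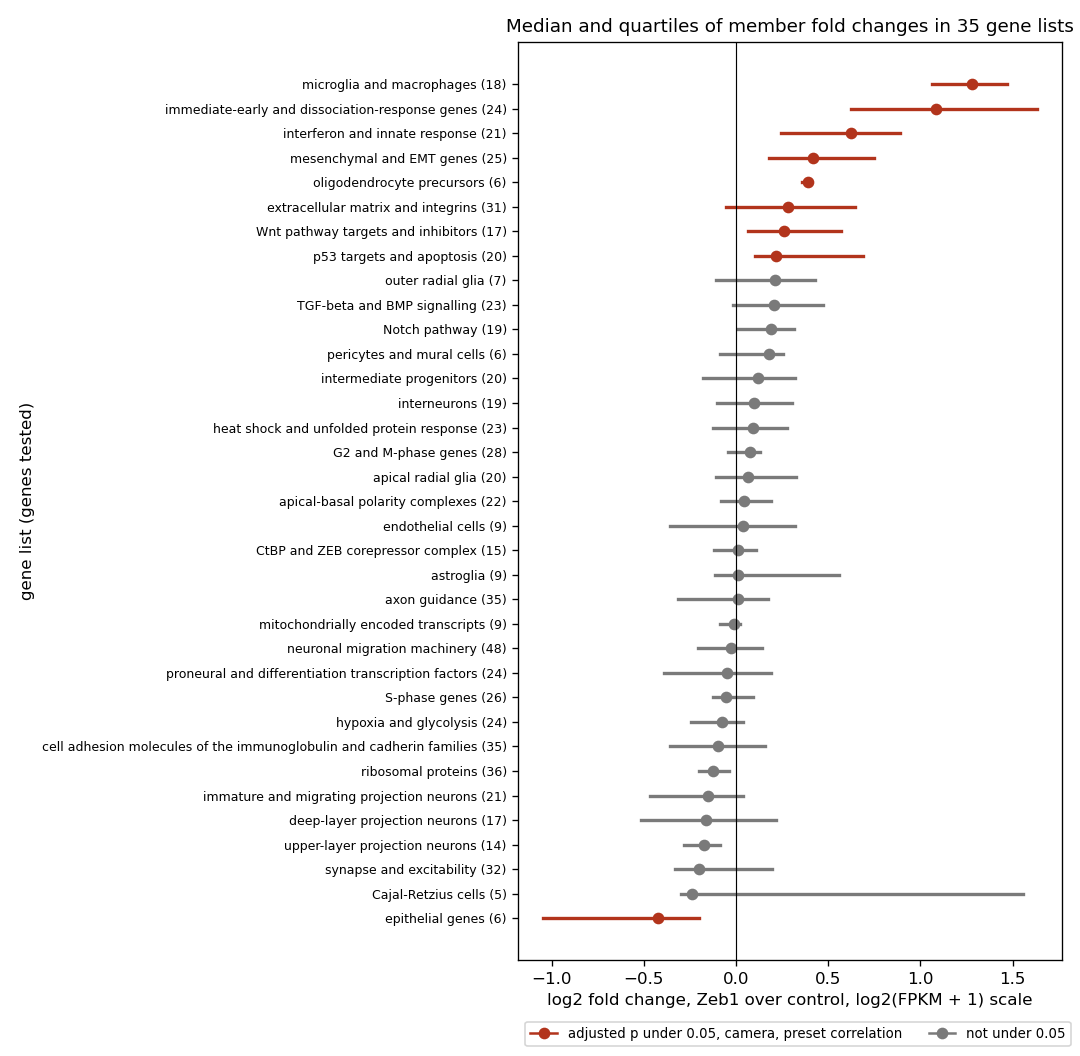
Median (point) and quartiles (line) of the log2 fold changes of the tested members of each of 35 gene lists, Zeb1 over control on the log2(FPKM + 1) scale, with the number of genes tested in parentheses. The microglia and immediate-early lists have the highest medians, 1.28 and 1.08, and the epithelial list has the lowest, -0.42.

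Immediate-early and dissociation-response genes rose as a set, with 24 of 24 members positive and a median log2 fold change of 1.08 (camera adjusted p = 4.13e-08, and adjusted p = 0.740 with an estimated correlation). Both Zeb1 libraries lay above both controls for 18 of the 24, against 2603 of all 14330 genes tested. In limma, 0 of the 24 passed over all genes or over the list alone, against 3 higher at an unadjusted p under 0.05. A split of the libraries by replicate number, which ignores the group, also called this list (camera adjusted p = 0.000409). The AP-1 gene Jun had 88.6 ± 14.2 FPKM in control and 305 ± 182 FPKM in Zeb1 cells. The zinc-finger gene Egr1 had 31.3 ± 10.4 and 155 ± 128 FPKM, and Klf6 had 22.0 ± 6.90 and 73.5 ± 42.9 FPKM. All 24 genes were highest in Zeb1 replicate 1. Without that library, the median was 0.56 and the adjusted p was 0.00224.

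Microglial and macrophage markers rose as a set, with a median log2 fold change of 1.28 over 18 genes (camera adjusted p = 7.97e-05, and adjusted p = 0.740 with an estimated correlation). Interferon and innate-response genes rose with them, with a median of 0.63 over 21 genes (camera adjusted p = 0.000353, and adjusted p = 0.740 with an estimated correlation). The split by replicate number also called the microglial and interferon lists (camera adjusted p of 3.45e-05 and 0.000474). In both lists 0 genes passed in limma over all genes or over the list alone, against 3 higher interferon genes and 0 microglial genes at an unadjusted p under 0.05. The lysosomal membrane gene Laptm5 had 87.8 and 18.2 FPKM in control replicates 1 and 2 and 155 and 118 FPKM in Zeb1 replicates 1 and 2, and the receptor gene Trem2 had 13.9, 4.71, 26.0 and 17.8 FPKM. Control replicate 2 was the lowest library for 17 of the 18 microglial genes, and the control libraries differed by a median of 1.82 on the log2 scale, more than the groups did. Without control replicate 2, the medians were 0.39 for the microglial and 0.18 for the interferon list (adjusted p of 0.105 for both), and without Zeb1 replicate 1 the adjusted p were 0.0541 and 0.0578. The interferon regulator Irf7 and the antiviral gene Rsad2 had log2 fold changes of 1.58 and 1.18, and that of Rsad2 was 2.29 with a pseudocount of 0.1.

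**Figure D3:**
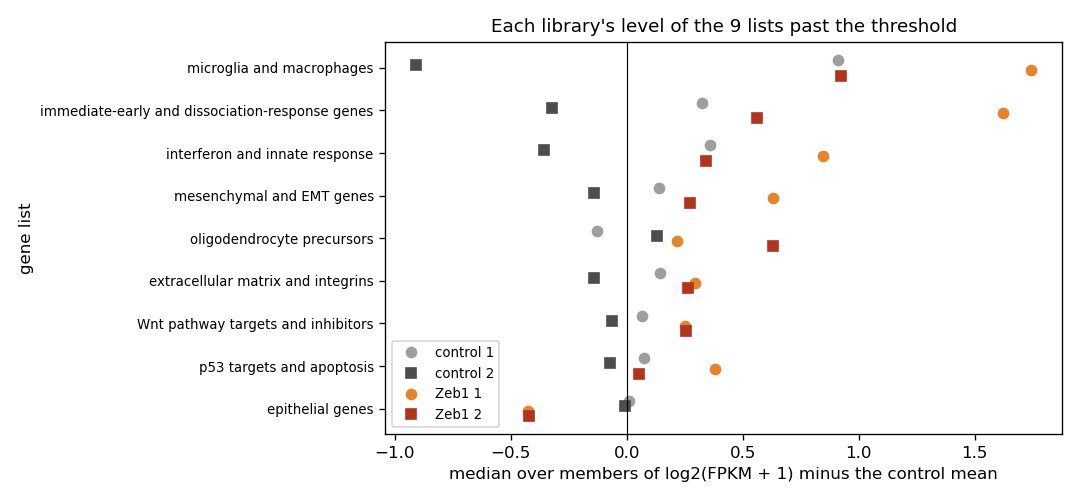
Median over the members of each called list of a library's log2(FPKM + 1) minus the control mean, with 1 point for each of the 2 control and 2 Zeb1 libraries. The microglial list lies at 0.91 and -0.91 in the controls and at 1.74 and 0.92 in the Zeb1 libraries, and the epithelial list lies at -0.42 in both Zeb1 libraries.

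Another 3 lists passed with the preset correlation by smaller shifts. Genes of oligodendrocyte precursors had a median log2 fold change of 0.39, with 6 of 6 positive and the early oligodendrocyte gene Bcas1 at 1.26 (camera adjusted p = 0.0360, and adjusted p = 0.740 with an estimated correlation). Targets and inhibitors of the Wnt pathway had a median of 0.26 over 17 genes (0.0428, and adjusted p = 0.740 with an estimated correlation), with the secreted protein gene Dkk3 at 0.94 and the ligand gene Wnt7b at -0.69. Genes of the p53 response and apoptosis had a median of 0.22, with 17 of 20 positive (0.0269, and adjusted p = 0.740 with an estimated correlation), among them the kinase gene Plk2 at 1.11 and the apoptosome gene Apaf1 at 0.77. In these 3 lists 0 genes passed in limma over all genes or over the list alone. At an unadjusted p under 0.05, 1 precursor gene, 2 Wnt genes and 2 p53 genes were higher and 1 Wnt gene was lower. The Wnt call ended without any 1 of the libraries (adjusted p of 0.0842 to 0.171). The precursor call ended without control replicate 1 (median 0.13, adjusted p = 0.387), control replicate 2 (0.69, 0.0576) or Zeb1 replicate 2 (0.22, 0.411), and its median was 0.63 without Zeb1 replicate 1. The p53 call ended without control replicate 1 (0.29, 0.141), control replicate 2 (0.14, 0.113) or Zeb1 replicate 1 (0.05, 0.210), and its median was 0.38 without Zeb1 replicate 2. Without a filter, all 3 calls ended, with medians of 0.07 for the 12 precursor genes (0.163), 0.09 for 24 Wnt genes (0.242) and 0.15 for 26 p53 genes (0.117). Quantile normalization ended the precursor (0.0816) and Wnt (0.0611) calls, and a mean of at least 5 FPKM ended the Wnt call (0.0742).

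The remaining lists did not pass the set test with all 4 libraries. The Notch list had a median of 0.19 (camera adjusted p = 0.188), with the receptor-like gene Dner at 1.06 and the ligand gene Jag2 at -0.83, and TGF-beta and BMP signalling one of 0.21 (0.153). Cell-cycle genes showed medians of -0.06 for S phase (0.877) and 0.08 for G2 and M phase (0.612), and the CtBP and ZEB corepressor list one of 0.01 (0.923). The medians were -0.07 for hypoxia and glycolysis (0.196), -0.12 for ribosomal proteins (0.175), -0.01 for mitochondrially encoded transcripts (0.941) and 0.09 for heat shock and the unfolded protein response (0.923). The heat shock list passed as lower without Zeb1 replicate 1 (-0.23, 0.0491) and as higher without Zeb1 replicate 2 (0.42, 0.00923). Ribosomal proteins passed as lower without Zeb1 replicate 1 (-0.27, 0.00486), the G2 and M-phase list as higher without Zeb1 replicate 2 (0.29, 0.0153), and the Notch list as higher at a mean of at least 5 FPKM (0.23, 0.0486). Among other cell types, they were 0.01 for astroglia (0.612), 0.04 for endothelial cells (0.923) and 0.18 for pericytes and mural cells (0.451). In these 12 lists, 0 genes passed in limma over all genes or over the list alone. At an unadjusted p under 0.05, the most were 1 higher and 2 lower in the Notch list and 3 lower in the hypoxia and glycolysis list. Cajal-Retzius cells had a negative median of -0.24 and a positive mean of 0.81 over 5 genes (0.245), with Ebf3 and Nhlh2 higher when adjusted over the list alone (0.000238 and 0.0155). With 1 library left out, these lay between 0.00728 and 0.0182 for Ebf3 and between 0.0396 and 0.116 for Nhlh2, which passed only without Zeb1 replicate 2. Reln, the marker secreted by those cells, had a log2 fold change of -0.38. Fewer than 5 genes were tested in the meningeal, choroid plexus and erythroid lists. In the first, Fbln1 passed over the list of 4 alone (0.00442, and 0.0230 to 0.0764 with 1 library left out, ending without either control), and in the other 2 lists, of 3 and 4 genes, 0 passed in limma, with 0 at an unadjusted p under 0.05.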

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

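Testing protein-coding genes alone was chosen after the data were seen, and the other alternatives were planned. Under pseudocounts of 0.1 and 0.5, rescaling to the same total, median-of-ratios scaling, quantile normalization and limma without the trend, 11 to 18 genes were higher and 16 to 18 lower, against 12 and 16, and 27 or 28 of the 28 genes were shared. A 2-fold minimum left 12 and 16. Without a filter, 28492 genes were tested, and 1 was higher and 0 lower in limma (964 and 977 at an unadjusted p under 0.05). With a mean of at least 5 FPKM, 10 were lower. With robust moderation 20 were higher. With a replicate block, 5 were higher and 6 lower. Protein-coding genes alone gave 3 higher and 0 lower in limma (582 and 547 unadjusted). Leaving out 1 library gave 0 genes in either direction in limma, with 323 to 791 higher and 334 to 582 lower at an unadjusted p under 0.05. That is a fit with fewer samples.

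The count of protein-coding genes higher when tested alone, 3, fell to 0 without a filter and to between 0 and 1 when a library was left out, where the 1 was Zeb1 without control replicate 1. With a replicate block, it was 587, and 270 were lower against 0. The replicate numbers are only known to be shared, and the deviations from the group means had a correlation of 0.0833 over all tested genes and 0.368 over protein-coding genes, across genes that are not independent replicates. The block fit of protein-coding genes alone also called Neurod1, Pard3, Pard6b and Tbr1. The block fit over all genes, adjusted over the study genes alone, ended the calls of Neurod1, Pard6b and Tbr1. Both fits leave 1 residual degree of freedom. The degrees of freedom that limma borrows across genes were 25.6 in the protein-coding block fit, against 4.07 without the block. Over all genes they were 2.23, against 1.96. The higher protein-coding counts came with that larger borrowing, and whether it alone accounts for them was not tested.

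The Zeb1 log2 fold change was 7.80 without a filter (adjusted p = 0.229) and 7.80 with a replicate block (0.0735), both no longer past the threshold. Leaving out 1 library gave 7.35 to 8.24, with adjusted p of 0.116 to 0.330. The adjusted p was between 0.00318 and 0.0226 under the other alternatives.

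Of the lists, 9 were called. The count was 5 without a filter, 0 with camera and an estimated correlation (0 unadjusted) and 0 with fry (4 unadjusted). Leaving out 1 library gave 2 to 14 lists, with 2 without control replicate 2, 5 without Zeb1 replicate 1, 6 without control replicate 1 and 14 without Zeb1 replicate 2. The remaining alternatives gave 6 to 9. Robust moderation was not run for lists, since camera has no such option. The causes were not tested.

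For the 187 other named genes, 2636 of 2746 values under alternatives kept their direction and side of the threshold, 83 fell short of it, 3 newly passed and 24 turned direction, in 16 genes. Quantile normalization turned Enkur (-0.0235) and mt-Co1 (-0.23). Leaving out 1 library gave log2 fold changes of both signs, from -0.60 to 0.0013 for Cacna2d2, -0.31 to 0.12 for Ctbp1, -0.16 to 0.39 for Dcx, -0.35 to 0.53 for Enkur, -0.47 to 1.13 for Hba-a1, -0.17 to 1.30 for Hbb-bt, -0.36 to 0.46 for Hes5 and -0.0094 to 0.65 for Igf2. The range was -0.25 to 0.0602 for Nes, -0.25 to 0.46 for Pax6, -0.012 to 0.49 for Rrm1, -2.36 to 1.46 for Ttr, -0.13 to 0.44 for mt-Co1, -0.41 to 0.71 for mt-Nd5, -0.48 to 0.20 for mt-Nd6 and -0.30 to 0.13 for mt-Rnr2. The cause was not tested. None of these 16 genes passed the test over all genes in limma. Absolute depth is unknown, so its limit on low values cannot be given.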

Other observations

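All tests in this part were chosen after the results were seen, and the genes of this paragraph were chosen after their values were seen. The Ebf genes, which encode helix-loop-helix factors of the same family, differed among themselves. Beside Ebf3, Ebf2 had 0.108 and 0.0594 FPKM in the controls and 1.07 and 1.10 FPKM in the Zeb1 libraries, below the level for testing, while Ebf4 had 10.6 ± 0.0357 and 9.83 ± 0.779 FPKM. Ebf1 had 0.996 and 4.03 FPKM in the controls and 0.673 and 0.969 FPKM in the Zeb1 libraries. Within 1 Mb of Zeb1 on chromosome 18, Svil, which encodes the actin-binding protein supervillin, had 2.21 ± 0.0762 and 7.33 ± 0.384 FPKM, a log2 fold change of 1.37 with a limma adjusted p of 0.266 over all genes. The other tested genes in that range, Epc1, Arhgap12, 9430020K01Rik, Kif5b, Zfp438 and Rab18, had log2 fold changes of 0.46, 0.41, 0.32, 0.10, -0.05 and -0.25. Some transcripts followed the replicate number and not the group. Gapdh had 22.7 and 24.7 FPKM in the replicates numbered 1 and 77.9 and 66.5 FPKM in those numbered 2, control first, and Mir6236 had 2265 and 542 against 21.4 and 10.4 FPKM.

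Short noncoding genes made up 25 of the 28 genes called. The tables argue against Zeb1 as their source, since 1 of the splits of the libraries that ignore the group called 28 short genes, and the other 25. The same few reads in both libraries of a group remain a candidate explanation. Among short genes that were not called, the control values stood in a ratio of whole numbers up to 4 within 0.5% in 62.8%, against 3.98% of protein-coding genes. Of those 152 short genes, 51 had equal values after depth was removed, and the depth estimate was itself taken from short genes. The share was 24 of 25 among those called, which the test selects for close replicates.

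The 4 libraries can be split into pairs in 3 ways, too few for a share under 0.05. The real split called 28 genes and the highest other 29, and 3 of the 3 splits gave at least 28. For protein-coding genes tested alone, the real split called 3 and the highest other 0 in limma (765 at an unadjusted p under 0.05), so 1 split gave as many. For gene lists, the real split called 9 and the highest other 9, so 2 splits gave as many.

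The microglial, immediate-early and interferon lists were higher in the Zeb1 libraries. More microglia or macrophages in some libraries are a candidate source of the microglial list, of which 17 of 18 genes were lowest in control replicate 2. So were 21 of 24 immediate-early and 16 of 21 interferon genes, so this count cannot tell a cell type from another shared cause. A sort for fluorescence is meant to remove cells that lack the plasmid, but its purity was not measured here. All 18 microglial genes reached the level for testing, with Laptm5 at 18.2 to 155 FPKM. Whether microglial RNA is also a source of the immediate-early list stays open. The median log2 difference of replicate 1 minus replicate 2 was 0.65 for the immediate-early and 1.82 for the microglial list between the controls, and 1.27 and 0.90 between the Zeb1 libraries, and other cells also express immediate-early genes. Zeb1 as the source of the immediate-early list stays open. Of its 24 genes, 18 were above both controls in both Zeb1 libraries, but 21 were lowest in control replicate 2 and 24 highest in Zeb1 replicate 1. The split by replicate number also called the list (camera adjusted p = 0.000409). That split also called the microglial (3.45e-05), interferon (0.000474), mitochondrial (7.31e-06) and heat shock (0.000409) lists, and the remaining split called the microglial list (0.0391). Dissociation, which the immediate-early list is also named for, was not tested as a source.

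Ebf3, Nhlh2, Mmp2 and Fbln1 were higher in the Zeb1 libraries, and other cell types are candidate sources of their RNA. The tables argue against Cajal-Retzius cells for Ebf3 and Nhlh2, since the higher of the log2 fold changes of Reln and Calb2 was -0.24 and Reln, abundant in those cells, had 11.5 FPKM in control and 8.51 FPKM in Zeb1 cells, although Ebf2, also on that list, had higher values in both Zeb1 libraries. They argue against meningeal fibroblasts for Fbln1 and Mmp2, since Col1a1, Col1a2 and Col3a1, abundant in those cells, rose by 1.16 FPKM in sum, against 29.1 FPKM for Fbln1 and 10.3 FPKM for Mmp2. A response to Zeb1, direct or indirect, stays open and was not tested.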
